A study of Mus musculus with 495 samples.

How the data were processed

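Single cells of mouse embryonic pancreas were measured with Smart-seq, 1 well per cell on 7 plates. The deposited values are raw read counts per gene and cell, whole numbers with no normalisation, from 23002 genes and 495 cells. The authors used STAR, HTSeq and FastQC with the mm10 genome, per the submitters' processing notes; versions are not given in the sources used here, nor are the sort gates. Reads carry no molecular identifiers, so PCR copies count as reads, and strand is not marked, so overlapping and antisense genes and near-identical copies share reads. Every cell column was matched to 1 sample by its name. No pair of cells held identical values. Gene positions are from GRCm38, GENCODE M21.

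Groups follow the plate code, day and genotype in the labels, giving 4 groups: 143 cells of the Neurog3 code, 157 of the endocrine code and 66 of the duct code at E15.5, and 129 cells at E17.5. The column names of the table carry the knock-in strain word for all plates, EA06 and EA07 included, while the labels give another strain for those 2; the groups follow the labels. The labels name no animal, litter or culture, so each group is 1 sample and no test was run. Cells with at least 50000 counts and 1000 genes were kept, which removed 0 cells. Cells held 200152 to 1182889 counts (median 533363) and 1237 to 6047 genes. Summed counts were 69729426 in the Neurog3 group, 85879209 in the endocrine group, 29154048 in the duct group and 95204148 at E17.5. A floor of 3 counts over a group is 0.0430, 0.0349, 0.103 and 0.0315 CPM in that order.

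Counts were summed per gene and group, divided by the group total and given as counts per 1000000 counts (CPM). The log2 ratio of 2 groups used a pseudocount of 5 CPM, which understates the ratio of low genes. Levels carry exact Poisson intervals, shares exact Clopper-Pearson intervals and ratios exact binomial intervals, all at 95% and for counting error only. A share of 0 cells is given with the share that 3 cells of the total make, as a floor, and with the upper end of the exact interval. A gene at 0 counts in 1 group is given as at least N-fold against the floor. The comparisons, the filters, 27 gene lists (12 pathway, 15 cell type) and the rule for named genes were fixed before the data were examined. That rule took genes with at least 50 CPM in the higher group, at 10 CPM or more in 25% of its cells, and with every plate of that group above every plate of the other, and named the 12 with the largest ratio in each direction. It added up to 4 members of each list with the largest absolute ratio, and Neurog3, Sox9, Pdx1, Nkx6-1, Ins1, Ins2, Gcg, Sst, Ppy and Ghrl; a few other genes that the rule took are not reported here. Gm-numbered, Rik, ribosomal protein, mitochondrial, small RNA, spike-in, Xist and Y-linked genes were left out. Plates separate by chance in 33.3% of genes for 2 plates against 2 and in 66.7% for 1 against 2.

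A list member was measured at 20 CPM or more in either group. A list's median has an order-statistic interval and a percentile among 10000 random lists matched on level, as a description of these libraries; 3 list genes were missing from the table. Lists with fewer than 3 measured members were not summarised: the PP, immune, erythroid and neural crest lists in every comparison, the serotonin list against duct, the mesothelium and endothelial lists in the other 2 comparisons, and the mesenchyme and G2 and M lists at E17.5. The median of all genes was 0.13, 0.08 and 0.19 in the 3 comparisons, 0.07, -0.0144 and -0.00822 with TMM factors and 0.0476, -0.0181 and -0.0182 with DESeq2 size factors.

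Cells were clustered on log-normalised counts (10000 per cell), 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 with seed 0. A cluster took the class with the most fixed markers among its 30 leading genes, if at least 3 markers of that class were over 2-fold higher than in the other cells and no other class had more among the 10 leading genes; this scoring rule was written after a first look at the clusters. Doublets were not called. Cells were called positive for a hormone at 1000 CPM, for Neurog3 at 20 CPM, and cycling with 3 G2 and M genes at 20 CPM. Plates EA01 to EA04 and EA05 to EA07 were taken as 2 library batches from their titles and from the share of counts on Rn45s (20.6% to 23.04% against 8.83% to 10.3%), and ratios were given within a batch where it holds both groups.

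Alternatives were the mean of the cells' own CPM, edgeR TMM factors, DESeq2 size factors, pseudocounts of 1 and 20 CPM, no filter or a stricter one on cells, no filter on genes, other thresholds, clustering settings, thinning and each plate left out. After the data were seen, comparisons within a library batch and within sets of well rows, totals without Rn45s, leaving out well rows D and H of plates EA01 to EA03 (also within the batch, and for E17.5 without EA05), and 20 other seeds with other cell orders were added. On simulated counts with 200 changed genes of 23002, the estimate passed the midpoint of the simulated log2 change for 65 of 68 (95.6%) genes changed 2-fold against duct, 63 of 68 (92.6%) for endocrine against Neurog3 and 62 of 68 (91.2%) for E17.5, and for 100% of those changed 4-fold and 8-fold. The simulated cells of a group shared the same mean, with no difference between plates, well rows or cell classes. These rates thus do not say how well a change is found beside such differences. Work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.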

Results

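Single cells of the mouse embryonic pancreas were sequenced with Smart-seq, a plate-based method that reads whole transcripts and carries no molecular identifiers. The table held 495 cells. At the embryonic stage E15.5, cells came from plates coded Neurog3 (EA01 and EA03), plates coded endocrine (EA02 and EA05) and a plate coded duct (EA04), all from a strain with eGFP at the Neurog3 locus. At E17.5, cells (EA06 and EA07) came, as labelled, from a Neurog3-Cre strain with the Rosa-mTmG reporter (the column names of the table carry the knock-in word for every plate), in which Cre switches a cell from membrane tomato to membrane GFP. Counts per cell ranged from 200152 to 1182889, with medians of 496804 in the Neurog3 group, 533922 in the endocrine group, 438470 in the duct group and 742184 at E17.5. The labels named no animal or litter, so each group was 1 sample with no replicate check, and no test or p-value was computed. Intervals of levels, shares and ratios are exact 95% intervals and cover counting error only. Those of list medians come from the order of the list members, and with 3 to 5 members are the full range, which covers less than 95%.

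Neurog3, the transcription factor that commits pancreatic progenitors to the endocrine lineage, lies on chromosome 10 at 62133090 to 62134763 of GRCm38 (GENCODE M21). Its summed level was 2293 CPM (counts per 1000000 counts of the group; interval 2281 to 2304) in the Neurog3 group, 935 CPM (929 to 942) in the endocrine group, 0.137 CPM (0.0374 to 0.351, from 4 counts) in the duct group and 1859 CPM (1850 to 1867) at E17.5. At least 20 CPM were found in 85 Neurog3-group cells (59.4%, 50.9 to 67.6), 50 endocrine-group cells (31.8%, 24.6 to 39.7) and 77 cells at E17.5 (59.7%, 50.7 to 68.2). None of 66 duct-group cells reached it, where 3 cells would be 4.55% and the exact interval ends at 5.44%. The endocrine plates differed from each other: EA02 held 43 positive cells of 72 (59.7%, 47.5 to 71.1), and EA05 held 7 of 85 (8.24%, 3.38 to 16.2). The Neurog3 plates held 56.2% and 62.9%.

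**Figure D1:**
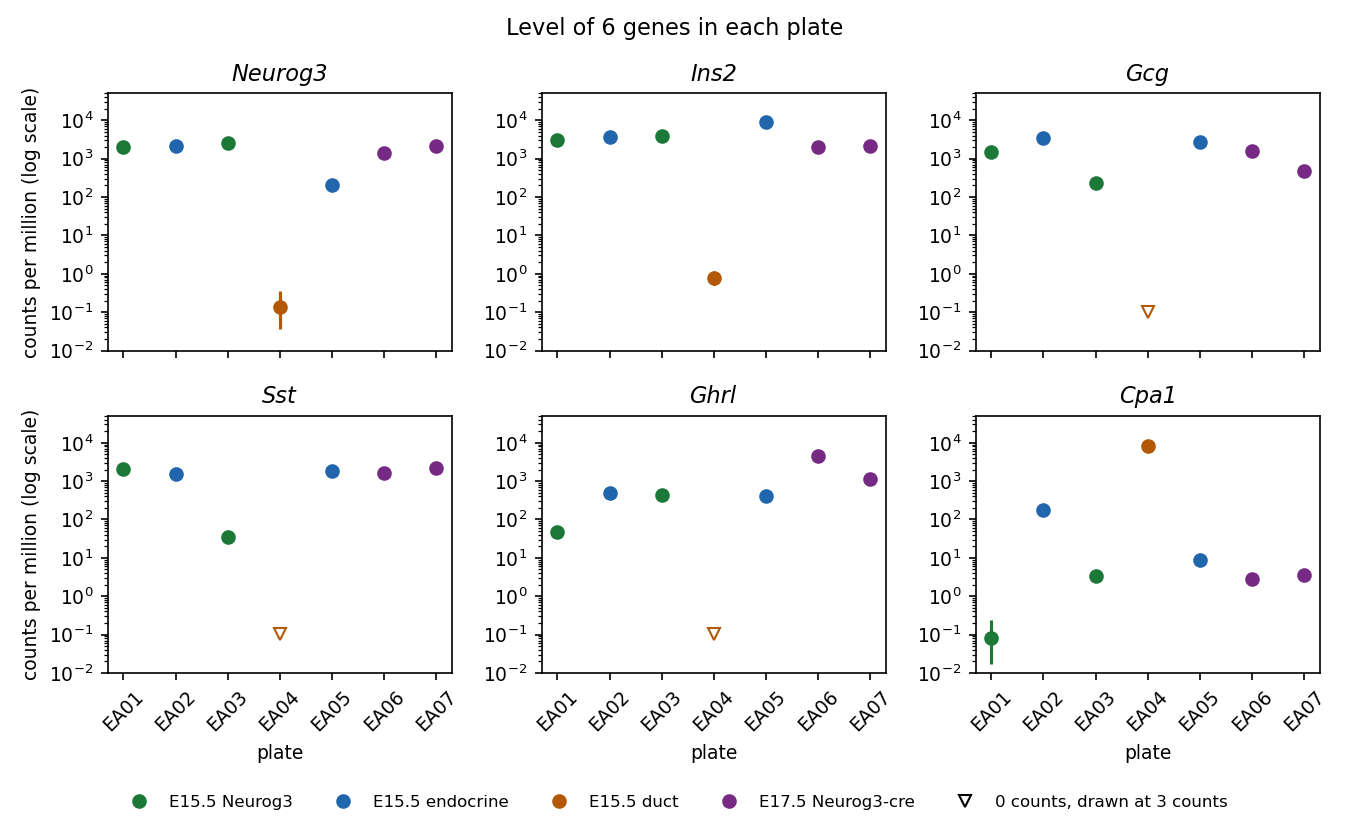
Summed level of 6 genes in each of the 7 plates, in CPM on a log axis, with exact Poisson intervals that are mostly smaller than the points; colours are the groups and an open triangle is a plate with 0 counts, drawn at 3 counts. Neurog3 stood at 2122 CPM in plate EA02 and 201 CPM in plate EA05, which carry the same endocrine code.

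The comparison of the Neurog3 with the duct code was made at E15.5. Endocrine genes were high in the Neurog3 group and almost unread in the duct group. Iapp, which encodes the islet peptide amylin, stood at 2814 CPM (2802 to 2827) against 0 counts, at least 27349-fold higher when set against a floor of 3 counts over the group. On the same floor Pyy (peptide YY) was at least 26868-fold higher, the amino acid transporter gene Slc38a5 at least 19927-fold and Pax4, a transcription factor gene of the beta and delta lineages, at least 8859-fold. The same floor gave at least 6535-fold for Scgn, 6379-fold for Chgb, 6255-fold for Chga, 4108-fold for Cck and 3904-fold for Pcsk2, genes of calcium sensing, granule content and prohormone cleavage. Neurod1, a direct target of Neurog3, was read at 688 CPM against 0.0343 CPM from 1 count (a log2 ratio without pseudocount of 14.29, counting interval 11.81 to 19.60). Hepacam2 was at 544 against 1.44 CPM. The cells of well rows D and H carried part of these levels: without rows D and H of plates EA01 and EA03, the log2 ratio was 7.88 against 9.14 for Iapp and 6.29 against 7.02 for Chga.

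In the duct group the leading genes were digestive enzymes of acinar cells. Pnliprp1, a pancreatic lipase-related gene, stood at 9467 CPM (9432 to 9503) against 1.28 CPM (1.03 to 1.57) in the Neurog3 group, and the carboxypeptidase gene Cpa1 (chromosome 6 at 30639218 to 30645363) at 8257 against 1.62 CPM. The chymotrypsinogen gene Ctrb1 was at 11400.4 against 15.7 CPM and the elastase gene Cela1 at 977 against 4.62 CPM (log2 ratio -6.06 without EA01 and -7.62 without EA03). With 0 counts in the Neurog3 group, Cel was at least 23463-fold lower there, Cela2a at least 10348-fold, Prss1 at least 9006-fold and Try10 at least 8883-fold. Amy2b was at 649 CPM against 0.0143 CPM from 1 count (a log2 ratio without pseudocount of -15.47, counting interval -20.77 to -12.99). Prss2 (547 against 0.516 CPM) and Nupr1 (497 against 0.272 CPM) were also among the leading genes.

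Of the lists fixed in advance, all 20 measured endocrine transcription factors were over 2-fold higher in the Neurog3 group (median log2 ratio 4.31, 2.64 to 5.08), with Rfx6 at 345 CPM against 0 and Fev, the regulator of serotonin genes, at 225 CPM against 0. All 10 measured hormones (median 7.67, 5.68 to 9.14, and 6.47 without EA01) and 19 of 21 secretory granule genes (4.24, 2.76 to 5.70) were higher as well. No hormone reached 20 CPM in the duct group, where 8 of the 10 had 0 counts. Each was thus measured through the Neurog3 group alone and could only be higher there. The same holds for members of other lists with 0 counts in the duct group. These were 10 of 20 transcription factors, 10 of 21 granule genes, 4 of 8 beta and 6 of 7 alpha members. The Neurog3 progenitor list had 12 of 13 members higher (3.39, 1.76 to 5.15), the precursor list around Fev had 5 of 5 (5.52), and the beta, alpha, delta and epsilon lists had 7 of 8, 7 of 7, 3 of 3 and 3 of 3. With members at 0 counts set at their bound, the medians were 7.55 for the transcription factors, 12.55 for hormones, 5.70 for granule genes, 3.42 for the progenitor list, 5.89 for the list around Fev, and 9.56, 9.71, 5.36 and 9.95 for the beta, alpha, delta and epsilon lists. With the pseudocount and without EA01, the delta list was at 2.99, the alpha list at 3.55 and Fev at 4.86, against 5.36, 4.19 and 5.52 with all plates. Without well rows D and H, hormones were at 6.42, granule genes at 3.57 and the beta list at 3.37, against 4.56 for the beta list in all wells. All of the medians with the pseudocount stood at or above percentile 99.7 among 10000 random lists matched on level. Nkx6-1 and Pdx1, which mark pancreatic progenitors and beta cells, were higher at 59.7 against 6.96 CPM and 61.3 against 11.3 CPM.

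All 13 acinar markers were over 2-fold lower in the Neurog3 group (median -6.49, -8.82 to -4.16), as were all 5 mesenchyme, 3 mesothelium and 5 endothelial markers measured, of 11, 4 and 8 listed (medians -4.19, -3.71 and -2.35), the mesenchyme median being -3.27 without EA01 and -6.17 without EA03. No mesothelium or endothelial marker reached 20 CPM in the Neurog3 group. Each was thus measured through the duct group alone and could only be lower in the Neurog3 group. The same holds for the 4 acinar markers with 0 counts in the Neurog3 group. At the bound the medians were -8.82 for acinar, -9.79 for mesothelium and -8.89 for endothelial markers. Collagen Col3a1 was at 23.8 against 775 CPM, Dcn at 6.48 against 552 CPM and Wt1, a mesothelial factor, at 0.889 against 72.03 CPM; without EA01 the log2 ratio was -3.82 for Col3a1 and -4.90 for Dcn, and without EA03 -7.28 and -6.80. The plate coded duct thus also carried acinar and mesenchyme markers and some of the markers listed for mesothelial and endothelial cells. No cluster took a mesothelial or endothelial name. Of the 11 duct markers, 6 were lower (median -1.04, -2.002 to 0.41), with Spp1 at 554 against 1702 CPM and Krt19 at 18.8 against 90.5 CPM, while Sox9, a factor of progenitors and ducts, differed little at 51.4 against 86.1 CPM.

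Proliferation genes were also lower in the Neurog3 group. Of the S phase list, 14 of 15 members were over 2-fold lower (median -2.45, -3.14 to -2.17), and so were all 16 of the G2 and M phase list (-2.94, -3.45 to -2.49), with Mki67 at 13.5 against 264 CPM and Top2a at 18.6 against 310.3 CPM (log2 ratio -4.38 without EA01). Cells with at least 3 G2 and M genes at 20 CPM made up 47 of 66 cells (71.2%, 58.7 to 81.7) in the duct group, 4 (2.80%, 0.767 to 7.01) in the Neurog3 group, 2 (1.27%) in the endocrine group and 2 (1.55%) at E17.5.

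Notch genes divided: Dll4, Hes6, Mfng and Rbpj were over 2-fold higher in the Neurog3 group, and Notch1, Notch2 and Hes1 over 2-fold lower (median 1.95, -2.44 to 4.24, 0.72 without EA03 and -0.19 with no gene filter). The imprinted list (3 higher, 4 lower, median -0.30), the keratin and adhesion list (3 higher, 4 lower, -0.30) and the unfolded protein response list (2 higher, 3 lower, -0.44) had members on both sides. Immediate early genes, which respond to cell dissociation, had 6 of 12 members higher (median 1.08, 0.49 to 1.45), with Dusp1 at 558 against 101.4 CPM. The beta cell maturation list had 6 of 7 higher (2.91, -0.16 to 4.75). The duct code had 1 plate, so code and plate cannot be told apart, and the median over all 7964 genes was itself 0.13.

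The comparison of the endocrine with the Neurog3 code was also made at E15.5. Glucagon was higher in the endocrine group: Gcg stood at 2977 CPM (2966 to 2989) against 906 CPM (899 to 913), a log2 ratio of 1.71. Nnat, an imprinted gene of insulin-producing cells, was at 1283 against 229 CPM (2.46), and Ins2 at 7016 against 3465 CPM (1.02). Neurog3 was lower in the endocrine group by its log2 ratio of -1.29, and Pax4 was at 354 against 912 CPM (-1.35). Plate EA05 was taken as another library batch than EA01 to EA03, from its title and its share of counts on the ribosomal RNA gene Rn45s. That share was 20.6% to 21.5% in EA01 to EA03 against 9.72% in EA05, and the batch was not tested otherwise. Within the batch, EA02 against EA01 and EA03, the log2 ratio was 1.91 for Gcg, 1.03 for Nnat, 0.07 for Ins2 and -0.11 for Neurog3, and Pax4 was at -0.40 without EA05. Gcg also differed between the Neurog3 plates, with a ratio of 3.68 without EA01 and 0.97 without EA03, while Neurog3 was at -3.48 and Pax4 at -2.61 without EA02. The well rows of these plates held different cells. In rows D and H Ins2 stood at 50577 CPM in EA01 and 113225 CPM in EA03, against 228 and 27.7 CPM in rows A, B, E and F, and without rows D and H the log2 ratio was 2.61 for Ins2. Row D of EA02 held 92684 CPM of Gcg, and within the batch without rows D and H the ratio was 0.68 for Gcg and 0.42 for Ins2. In rows A, B, E and F alone Gcg was at -4.95, which rests on row E of EA03 (1298 CPM there, and 0.203 and 0.0459 CPM in these rows of EA01 and EA02), and in rows C and G alone Pax4 was at 0.04.

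Among the other leading genes higher in the endocrine group were Tmsb15b2 (480 against 106.1 CPM), Tmsb15l, BC048546, Dbpht2, Tmem107 and Ppp1r1a, with log2 ratios of 1.82 to 2.13 and of 0.31 to 0.73 within the batch. The thymosin genes Tmsb15b2 and Tmsb15l are near-identical copies, so their counts may be shared. Akr1c13 (1.70), Zcchc18 (1.63) and Tshz1 (1.52) had within-batch ratios of 1.40, 1.18 and 1.17, while Tmem27 (1.63) and Slc7a2 (1.53) had 0.18 and 0.19. Lower in the endocrine group were D4Bwg0951e (47.8 against 182 CPM), Cer1, a secreted signalling antagonist gene (55.9 against 206 CPM), Insrr, a receptor of the insulin receptor family (149.4 against 420.2 CPM), Plcg1 (79.9 against 225 CPM), Ttll6 (73.1 against 204 CPM) and Igfbpl1 (46.7 against 131.1 CPM). Pik3r1, Eya3, Celf2, Myst2, Ptprk and Syne2 had log2 ratios of -1.47 to -1.36. Within the batch these 12 genes were at -0.36 (Ptprk) to -1.76 (Myst2). The rule for leading genes required every plate of a code to lie beyond every plate of the other. It thus fixed the sign of the within-batch ratios of leading genes in both directions, and only their size is a result. Without EA02, Ptprk and the 6 genes given with CPM were at -3.80 (Cer1) to -2.15 (Insrr), and without EA01 Zcchc18 was at 2.38, Myst2 at -0.67 and Eya3 at -0.83. In rows A, B, E and F alone Dbpht2 was at -0.79 and Slc7a2 at -1.48, and in rows C and G alone Ptprk was at 0.67 and Ttll6 at 0.40.

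By list, 4 of 11 hormones were over 2-fold higher in the endocrine group (Ins2, Gcg, Iapp and Npy) and 1 was lower (Gast), with a median of 0.86 (-0.89 to 1.71) that was 0.07 within the batch, where Iapp was at -0.14, and -0.56 in rows A, B, E and F alone. Without rows D and H, Iapp was at 2.26. Npy was at 1.20 without EA05, 2.62 without EA01 and 5.32 without EA03. The Neurog3 progenitor list had 5 of 13 members lower, among them Hes6, Mfng and Btbd17, and none higher; its median of -0.69 (-1.17 to -0.46) was 0.10 within the batch, where Btbd17 was also at 0.10, Hes6 at -0.07 and Mfng at -0.24, and -1.76 without EA02, where Btbd17, Hes6 and Mfng were at -3.05, -2.32 and -2.37. Beta cell maturation genes had a median of 0.72 (0.19 to 2.46) with Slc2a2, the glucose transporter gene, at 86.9 against 20.05 CPM, and 0.44 within the batch; without rows D and H Slc2a2 was at 2.58. Of the acinar list, 4 of 5 were higher in the endocrine group (median 2.18, and 3.37 within the batch), with Cpa1 at 72.7 against 1.62 CPM but at a log2 ratio of -0.04 in rows C and G alone; plate EA02 held the group's only acinar-like cell, and without it Cpa1 was at 1.08, and without EA05 at 4.77. Of the mesenchyme list, 3 of 4 were lower and 1, Vim, was higher (median -2.18, members -2.53 to 1.19, and medians of -2.44 within the batch and -3.11 without EA01). Neither group held a mesenchyme-like cell. Of all cells outside that cluster, 0.415% reached 10 CPM of Col1a1, 0.622% of Col3a1 and 1.87% of Col1a2. The 3 lower members are these collagen genes, so their difference rests on few cells. Endocrine transcription factors (18 of 20 within 2-fold, -0.19), granule genes (20 of 21 within 2-fold, 0.40) and the unfolded protein response (12 of 12 within 2-fold, 0.28) differed little. Imprinted genes had a median of -0.02 with 9 of 12 within 2-fold, while Peg10 and Nnat were higher and Igf2 lower.

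Other medians were -0.73 for the Notch list, where Hes1, Hes6 and Mfng were lower (-1.73 without EA02 and -1.35 without EA03, and -0.15 within the batch), -0.47 for the immediate early list, -0.29 for S phase, -0.18 for adhesion and keratins, -0.20 for the duct list and -0.47 for the precursor list around Fev. The G2 and M list had 3 measured members, all lower (-1.71, -2.58 without EA02 and -0.96 within the batch), the serotonin list 2 of 4 higher (0.67), the beta list 3 of 8 higher (0.75, and -0.03 within the batch), the alpha list 2 of 7 higher and 1 lower (0.73, and -0.28 within the batch), the delta list 1 of 3 higher (0.58), and the epsilon list 1 of 3 lower (-0.86). Ins1 (0.78), Ghrl (0.91), Ppy (0.66), Sst (0.58), Nkx6-1 (0.38), Pdx1 (-0.04) and Sox9 (-0.07) were within 2-fold over all plates. This depends on the plate: without EA01 Sst was at 5.42, Ghrl at 0.01 and Ppy at 1.64, without EA03 Sst was at -0.32, Ghrl at 3.12 and Sox9 at 0.40, and without EA05 Ppy was at -1.31 and Pdx1 at -0.67. Without EA05 the duct list was at 0.34, S phase at 0.30 and the unfolded protein response at -0.18. The delta list was at -0.32 without EA03 and 1.501 without EA01, where the serotonin list was at 1.40. Without EA02 the duct list was at -0.95, Hes1 at -2.87 and Pdx1 at 0.25. Without well rows D and H of EA01 to EA03, Ins1 was at 2.65, Sst at 1.72 and the beta list at 2.21.

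**Figure D2:**
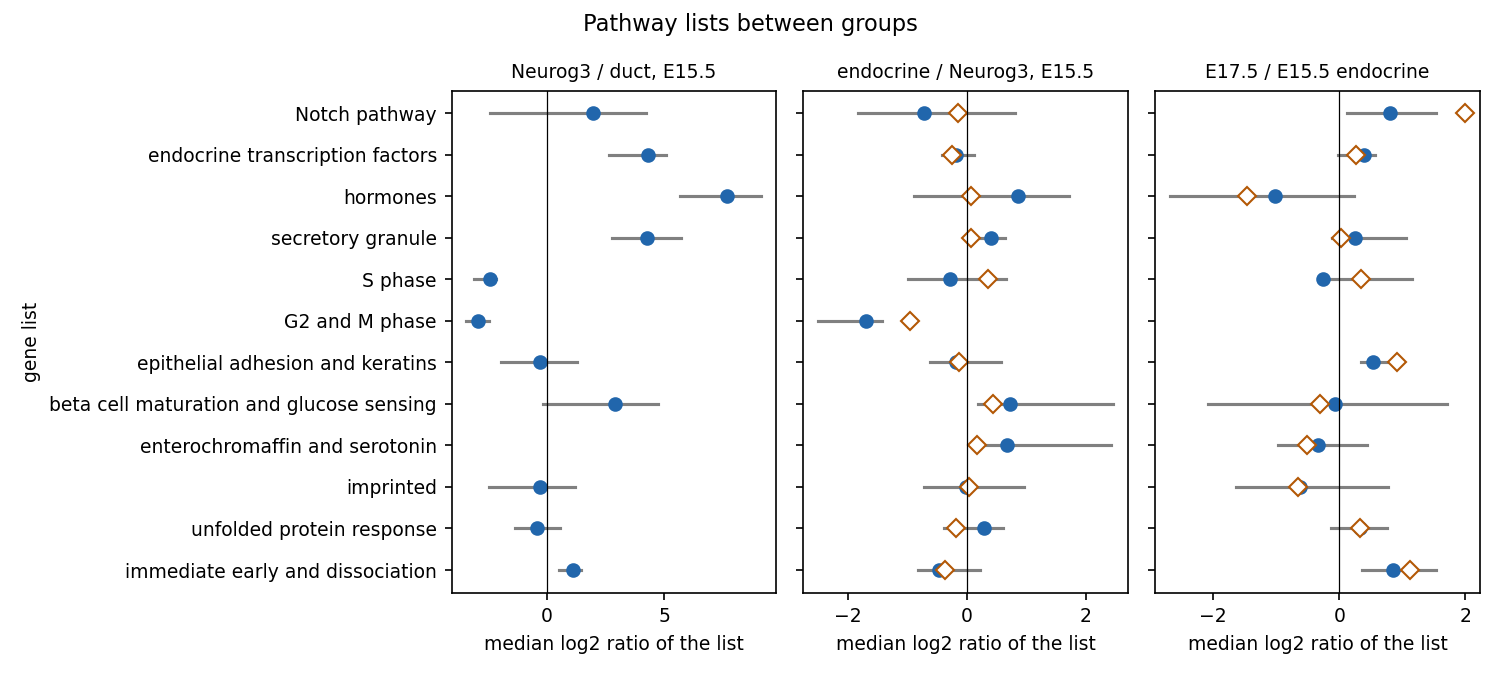
Median log2 ratio of each pathway list (points, with 95% order-statistic intervals) in the 3 comparisons. For lists of 3 to 5 measured members the line is the full range of the members and covers less than 95%. Open diamonds are the medians within a library batch, where a batch holds both groups. Hormones stood at 7.67 in the Neurog3 group against duct, and at 0.86 in the endocrine group against Neurog3, where the within-batch value was 0.07.

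In the comparison of E17.5 with the endocrine code of E15.5, strain, day, plate and sex mix differ together and cannot be told apart. The E17.5 cells read as female, while the endocrine plates held cells of both sexes, as given below. Over all plates, insulin and glucagon were lower at E17.5 and ghrelin higher. Ins1 lies on chromosome 19 at 52264297 to 52265476, Gcg on chromosome 2 at 62474530 to 62483650 and Ghrl on chromosome 6 at 113716119 to 113719880. Ins2 is annotated on chromosome 7 at 142678656 to 142743381, a span that includes transcripts running into the next gene, and Ins1 and Ins2 are close copies, so reads between them are uncertain. Ins2 stood at 2144 CPM (2135 to 2154) against 7016 CPM (log2 ratio -1.71, within the batch -2.08), Ins1 at 912 against 3095 CPM (-1.76, within the batch -1.98) and Gcg at 873 against 2977 CPM (-1.76, within the batch -1.63). Ghrl, the ghrelin gene of epsilon cells, stood at 2323 CPM (2313 to 2332) against 441 CPM (436 to 445), a log2 ratio of 2.38 and of 2.50 within the batch. All 4 epsilon markers were over 2-fold higher (median 2.73, members 1.76 to 4.63, and a median of 3.14 within the batch), including Mboat4, the enzyme that acylates ghrelin (261 against 26.4 CPM). The direction for insulin rests on EA05 and on well rows D and H of EA02: against EA02 without these rows, the log2 ratio was 0.66 for Ins2, 0.16 for Ins1 and -0.71 for Gcg. Against all wells of EA02 Ins2 was at -0.76 and Mboat4 at 2.38, and against EA05 alone Mboat4 was at 3.79; without EA07 Gcg was at -0.88 and Ghrl at 3.36, and without EA06 they were at -2.63 and 1.33.

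Reads of the transgenes differed as well. Cre was at 511 CPM at E17.5 and at 0 counts in the endocrine group, at least 14620-fold higher on a floor of 3 counts over the group, and the GFP transgene was at 1346 against 11.8 CPM (log2 ratio 5.28 against EA02 alone and 7.88 against EA05 alone). Other leading genes at E17.5 were the iron exporter gene Slc40a1 (164 against 6.72 CPM), AI846148 (61.2 against 2.65 CPM), Sox4, a factor of endocrine progenitors (203 against 20.8 CPM), Med25 (173 against 18.2 CPM), Jund (163 against 21.4 CPM) and the granule gene Chga (2627 against 452 CPM). Egln2, Csnk1g2, Tbc1d9b and Slc38a10 had log2 ratios of 2.50 to 2.78. Ttll6, a tubulin-modifying enzyme gene, had 0 counts at E17.5 against 73.1 CPM, at least 2321-fold lower. Rab4a (14.7 against 111.4 CPM), Tmsb15b2 (86.1 against 480 CPM), the granule gene Resp18 (52.5 against 221 CPM), Gfra3, a neurotrophic factor receptor gene (88.7 against 355 CPM), Pgap1, Anp32a, H2-T10, Rian and Atm were also lower, the last 5 with log2 ratios of -1.85 to -1.63. Plate EA07 carried much of several of these: without it the ratio was 0.57 for Chga, 0.74 for Sox4, 1.004 for Med25, 1.06 for Jund, 1.45 for AI846148, 1.11 for Egln2, 0.36 for Slc38a10, 1.47 for Csnk1g2, 1.88 for Tbc1d9b, -0.91 for Resp18, -1.05 for H2-T10 and -3.12 for Gfra3, while without EA06 Resp18 was at -3.23. Against EA02 alone it was -0.72 for Tmsb15b2, -1.87 for Rab4a, -1.02 for H2-T10, -0.97 for Pgap1, 3.43 for Csnk1g2, 3.36 for Tbc1d9b and -4.90 for Ttll6, which was -2.77 against EA05 alone. Without well rows D and H of EA02, Resp18 was at -1.14, and at 1.005 without EA05 as well; Chga was then at 3.50 and Slc40a1 at 4.94.

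Of the hormones, 6 of 11 were over 2-fold lower at E17.5 and only Ghrl was higher (median -1.03, -2.68 to 0.23, and -1.46 within the batch), with Iapp at 2965 against 6039 CPM; without EA05 the Iapp log2 ratio was 0.21. Against EA02 without rows D and H, the hormone median was 0.65 and Iapp was at 1.16. Immediate early genes had 6 of 14 members higher and none lower (0.86, 0.36 to 1.53, and 1.12 within the batch), with Jun at 624 against 99.5 CPM (0.50 without EA07, 3.41 without EA02 and 1.82 without EA05). Duct markers had 5 of 11 higher (0.94, 0.42 to 1.96, and 1.68 within the batch), with Spp1 at 1100.2 against 279 CPM (0.64 against EA02 alone and 5.74 against EA05 alone) and Sox9 at 102.5 against 48.6 CPM. The granule list had 6 of 21 higher and 2 lower (0.24, and -0.01 without EA07), imprinted genes 3 of 11 lower (-0.62), the beta list 4 of 8 lower (-0.83, and -1.17 within the batch), and the alpha list 1 higher and 3 lower of 7 (-0.11). Of the Neurog3 progenitor list, 3 of 14 were higher (0.50, -0.18 to 1.08); this median was 1.79 within the batch, where EA05 alone stands for E15.5, -0.44 against EA02 alone and -0.09 without EA07. Neurog3 itself had a log2 ratio of 0.99, and of 3.17 within the batch, but -0.19 against EA02 alone, where hormones were at -0.41, the beta list at -0.14 (0.41 without rows D and H) and the alpha list at 0.48.

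The remaining lists had these medians: endocrine transcription factors 0.39 (2 of 20 higher), adhesion and keratins 0.53 (2 of 13 higher), Notch 0.80 (2 of 5 higher, and 1.99 within the batch), the unfolded protein response 0.33 (1 of 12 higher), beta cell maturation -0.07 (1 higher, 1 lower of 7), serotonin -0.34 (0 of 4 beyond 2-fold), S phase -0.27 (2 higher, 1 lower of 9), the delta list 0.23 and the precursor list around Fev 0.44. The acinar list had 3 of 5 lower (-1.13, and 0.17 within the batch). Sst (0.23), Pdx1 (0.39), Nkx6-1 (-0.18) and Ppy (-0.41) were within 2-fold over all plates. Without EA07, adhesion and keratins were at -0.12, Notch at 0.11, the unfolded protein response at -0.36, the delta list and Sst at -0.09 and Pdx1 at -0.33, and against EA02 alone beta cell maturation was at 0.52, serotonin at 0.24, the acinar list at -2.18, Pdx1 at 1.02 and Ppy at 1.57. Ppy was at -1.53 without EA06 and 0.60 without EA07. Against EA02 without well rows D and H, Sst was at 1.90 and Ppy at 1.80. Without EA02, S phase was at 0.16, and the acinar list was at -0.34 there and at -1.79 without EA07. The median over all 8031 genes was 0.19, which these ratios include; it was -0.01 with TMM factors, edgeR's scaling that trims extreme genes.

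Hormone-positive cells had at least 1000 CPM of a hormone. Insulin was positive in 21 Neurog3-group cells (14.7%, 9.33 to 21.6), 36 endocrine-group cells (22.9%, 16.6 to 30.3) and 15 cells at E17.5 (11.6%, 6.66 to 18.5). Well rows D and H held 5 of the insulin-positive cells of EA01, 3 of those of EA02 and 3 of those of EA03. The endocrine plates held 11.1% (EA02) and 32.9% (EA05). Gcg was positive in 3.50%, 10.8% and 3.88% of the 3 groups in that order, Sst in 6.29%, 7.64% and 11.6%, and Ppy in 3.50%, 8.28% and 6.20%. Of the Neurog3 plates, EA01 held 10.96% Sst-positive cells and EA03 1.43%. Ghrl was positive in 5 (3.50%, 1.14 to 7.97), 6 (3.82%, 1.42 to 8.13) and 20 cells (15.504%, 9.73 to 22.9), with 24.6% in EA06 and 8.33% in EA07. At least 2 of the 5 hormones were found in 4.90%, 10.2% and 7.75%, and in 0.699%, 1.27% and 0.775% at 10000 CPM. The share with at least 2 hormones was 8.22% in EA01 and 1.43% in EA03, and without well rows D and H of plates EA01 to EA03 the Neurog3-group share was 1.49%. None of the 66 duct-group cells was positive for any of the 5 hormones, where 3 cells would be 4.55% and the exact interval ends at 5.44%. The sort, whose gates are not given in the sources used here, sets all shares of cells.

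Clustering gave 13 clusters, 12 of which took a name from the fixed markers; doublets were not called. Genes that define these clusters differed in level between groups, so each share describes its own group and no order between groups is read from them. In the duct group, 43 of 66 cells were acinar-like (65.2%, 52.4 to 76.5), 13 mesenchyme-like (19.7%, 10.9 to 31.3) and 10 duct-like (15.2%, 7.51 to 26.1), and none fell in an endocrine class. Beta-like cells made up 11.2% of the Neurog3 group, 22.3% of the endocrine group and 7.75% at E17.5, and alpha-like cells 3.50%, 8.92% and 3.10%. The alpha-like shares were unstable too: they moved with the clustering resolution, the variable genes and the plate left out, as given below. Of the beta-like cells, 5 of EA01, 4 of EA02 and 3 of EA03 were cluster 12, all from well rows D and H. Clustering again without these rows gave beta-like shares of 8.21%, 20.5% and 8.53%. Delta-like cells made up 2.10%, 3.18% and 8.53%, and duct-like cells 1.40%, 0.637% and 6.20%. Acinar-like cells numbered 1 in the endocrine group. Epsilon-like cells made up 2.80%, 2.55% and 17.1% (11.01 to 24.7), a name that was lost at resolution 0.5 and with 1000 or 4000 variable genes.

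Neurog3 progenitor-like cells made up 27.3%, 17.8% and 13.2%, and Fev precursor-like cells 29.4%, 10.2% and 28.7%. The latter name is weak at E15.5: all of these cells lay in cluster 2, which Neurog3 leads and where Fev is not among the 30 leading genes, and 31.3% of those of the endocrine group held Fev, against 82.9% of the unnamed cluster. The name is weak at E17.5 too, where most of these cells lay in cluster 6, which Chgb leads. Among the 30 leading genes of cluster 6 was 1 marker of the class, Fev. The border between these classes and the unnamed cluster (22.4%, 33.8% and 15.504%) was unstable: over 20 other seeds and cell orders, progenitor-like cells ranged from 21.7% to 55.9%, 15.3% to 28.03% and 12.4% to 18.6%, and Fev precursor-like cells from 0% to 30.8%, 0% to 16.6% and 23.3% to 30.2%. At E17.5 most of these cells lay in clusters found only in plate EA07 (13 of the 17 progenitor-like and 30 of the 37 Fev precursor-like cells), which may be that plate.

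**Figure D3:**
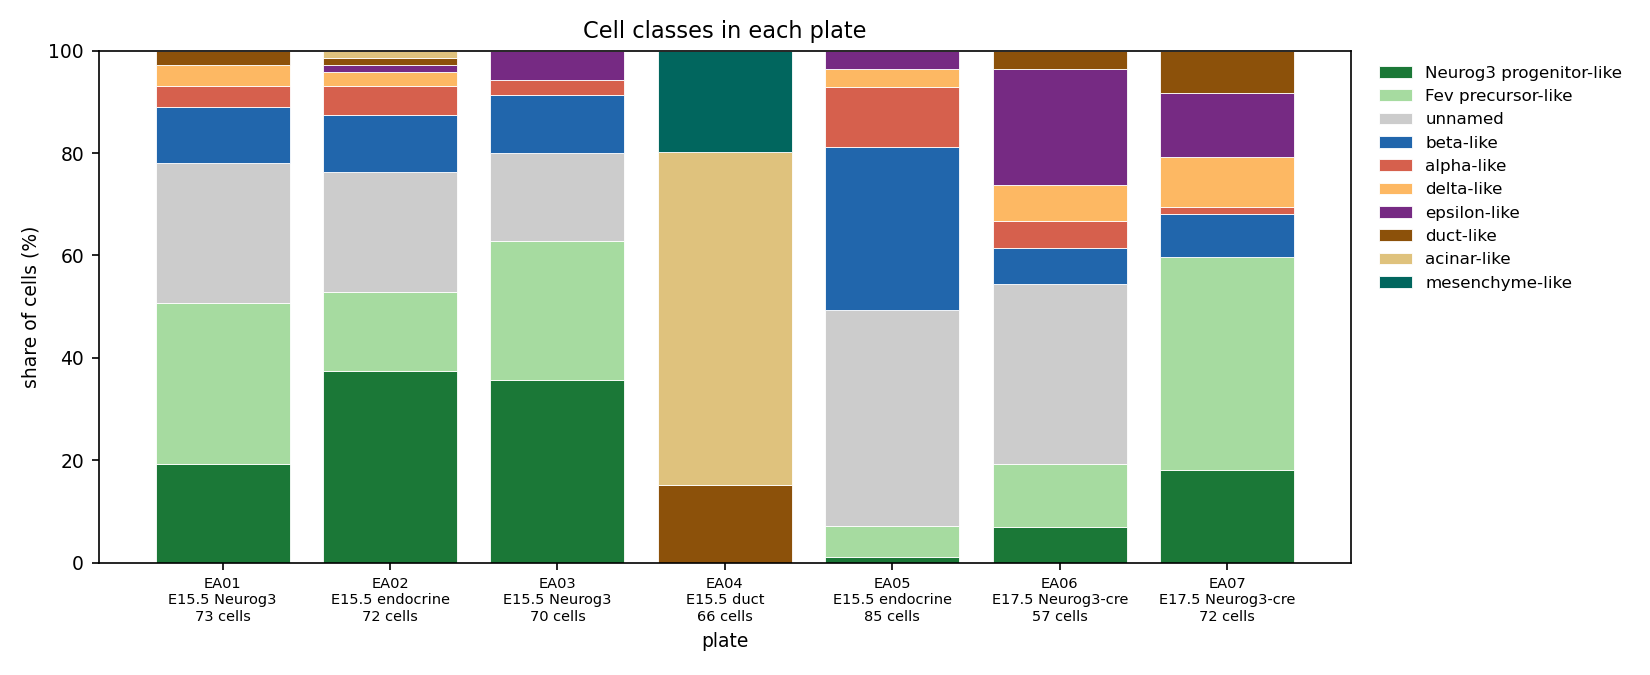
Share of cells in each class (stacked bars, 0 to 100% of the cells of a plate) in the 7 plates, with the group and number of cells under each bar. Plate EA04 holds acinar-like, mesenchyme-like and duct-like cells, and plate EA05 holds fewer Neurog3 progenitor-like cells than plate EA02.

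Within a class, E17.5 and the E15.5 endocrine group were set side by side where both held at least 10 cells, leaving out as results the genes that define a cluster. In beta-like cells (10 against 35) the chaperone gene Hyou1 stood at 684 against 73.7 CPM (a log2 ratio of 1.46 without EA07 and 2.21 without EA05). The unfolded protein response list, 3 of whose members are among the leading genes of cluster 3, had 6 of 12 members higher (median 0.98, 0.55 to 1.53). Pdx1 was at 211 against 100.7 CPM. Immediate early genes had 9 of 14 members higher (1.11, 0.57 to 1.98), and beta cell maturation genes, 3 of whose members are among those leading genes too, had a median of 0.63 (-0.58 to 1.41). Hormones had 6 of 10 members lower (-1.84, -5.60 to -0.13), a list that holds genes defining these clusters, and its median was -1.16 without EA05 and -2.69 without EA07. The E15.5 cells lay in clusters 3 (31) and 12 (4), and the E17.5 cells in cluster 3. Without plate EA07, Pdx1 had a log2 ratio of -0.01 and the maturation list a median of -0.18. The median over all genes in beta-like cells was then -0.47, so all genes shifted too.

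Neurog3 progenitor-like cells (17 against 28) had 12 of 15 granule genes higher (median 2.69, 1.04 to 3.71); here clusters 1 (4) and 10 (13) stood against cluster 1. Fev precursor-like cells (37 against 16) had 14 of 21 granule genes higher (2.11, 0.86 to 3.60), but granule genes define cluster 6; here clusters 2 (7) and 6 (30) stood against cluster 2. Endocrine transcription factors had medians of 0.85 and 0.17 in these classes, the latter -0.04 with DESeq2 size factors, and members of the list define cluster 2. Without plate EA07 the granule medians were -0.03 and -0.14 and that of the transcription factors in progenitor-like cells 0.45. The median over all genes was then -0.61 in progenitor-like and -0.24 in Fev precursor-like cells, so all genes shifted too. Without EA02 the transcription factors in progenitor-like cells were at 3.24. There E15.5 held 1 progenitor-like cell, of EA05, and the median over all genes was 3.16. Without EA05 the granule median in Fev precursor-like cells was 2.96. With all plates the median over all genes was 0.35 in progenitor-like, 0.47 in Fev precursor-like and 0.03 in beta-like cells. Alpha-like (4 against 14), delta-like (11 against 5) and epsilon-like cells (22 against 4) were too few to compare.

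The plates of E15.5 held cells of both sexes, and those of E17.5 cells that read as female. A Y-linked gene at 20 CPM was found in 28.2% to 35.7% of the cells of the 5 plates of E15.5 and in 0 of 57 and 0 of 72 cells of EA06 and EA07, which allows up to 5.26% and 4.17%. Xist, which silences an X chromosome in female cells, was found in 42.9% to 58.8% of the cells of the earlier plates and in 87.7% and 94.4% of those of EA06 and EA07.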

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

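The tests of chance placement, of a batch with low Neurog3, of how EA02 was filled and of GFP beside Neurog3 were chosen after the result was seen, and the sets of well rows were formed after the shares per well row had been seen.

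In well rows D and H of plates EA01 to EA03, 13 of 15 cells held the GFP transgene at 10 CPM or more (86.7%, 59.5 to 98.3), above the duct plate, where 0 of 66 cells did, which allows up to 4.55%. None of the 15 cells of well rows D and H had Neurog3 or a Y-linked gene at 20 CPM, 14 had Xist, and 11 were insulin-positive. All 12 cells of cluster 12 were among these 15 cells. In the other rows of these plates 33 of 200 cells held GFP (16.5%).

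Well rows of plates EA01 to EA03 held different cells. Neurog3 was positive in 80.4%, 82.6% and 79.5% of rows A, B, E and F and in 19.05%, 25% and 39.1% of rows C and G. With rows sorted by their share in EA01 alone, the smaller gap of EA02 and EA03 was 44.9 points, with intervals apart in both plates, which argues against chance placement. Thinned to 50000 counts the smallest gap was 42.7 points, which argues against depth. For rows D and H, the imprinted list without Nnat had a median log2 ratio of -2.49 (-5.26 to 1.64) in 11 insulin-positive cells against 28 of EA05, so a later stage of these cells may apply but stays open; no biological explanation given by the design was tested.

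Plate EA02 lay nearer the Neurog3-coded plates than EA05 did. Plates EA06 and EA07, taken as the library batch of EA05, had at least 57.9% positive cells. They differ from EA05 in strain, day and sex mix, so a batch with low Neurog3 stays open. Within the same well rows EA02 differed from EA01 or EA03 by at most 14.1 points, so a candidate explanation is that EA02 was filled by row in the way of those plates; a wrong label stays open.

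GFP reads were found in few cells of E15.5. Thinned to 50000 counts, 100% of E17.5 cells still held GFP, against 15.7% of the E15.5 cells outside the duct plate, which argues against depth. In plates EA01 to EA03 without rows D and H, GFP was found in 25.8% of Neurog3-positive cells and 0 of 72 negative cells, a gap of 25.8 points. All of these GFP-positive cells lay in rows A, B, E and F, where 30% of 110 Neurog3-positive (21.6 to 39.5) and 0 of 26 negative cells held GFP. In rows C and G 0 of 18 Neurog3-positive cells did (interval to 18.5%). The level of Neurog3 in positive cells was not compared between these rows. Rows C and G thus cannot tell whether the Neurog3 transcript alone sets GFP reads. In rows D and H, left out here, 13 of 15 cells held GFP and none of the 15 was Neurog3-positive. The strains carry GFP at different loci, and this difference stays open as untested.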

How the results depend on the processing

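The tests within a library batch, by well row, without well rows D and H, without Rn45s in the totals and over other seeds were chosen after the data were seen; the other alternatives were fixed before the data were examined. No paired analysis was possible because the labels give no animal or replicate number that pairs groups and each group is 1 sample. Of the medians of the main lists, 4 alternative values moved beyond the interval of the reported median, 12 changed sign and the others stayed within it; of the other lists, 851 stayed, 48 moved and 3 with a reported ratio over 2-fold changed sign. Of the single genes, 305 stayed within their narrow counting interval, 1715 lay beyond it and 20 with a reported ratio over 2-fold changed sign. That interval is for the ratio without the pseudocount, so the reported ratio of many genes itself lies outside it. Values beyond it thus include unchanged ones, such as most of those with no cell filter, and are not a count of changes with processing. Ratios reported within 2-fold that changed sign are among those that stayed, moved or lay beyond the interval. Over ratios of any size, 52 values of the other lists and 44 of the genes had the other sign. The leading genes could not change sign with a plate left out or within a batch, because the rule that named them had separated the plates. For them these settings give no check of direction. Of the shares of cells, 735 stayed and 120 moved in named classes and markers, and 47 and 20 in the unnamed cluster. All of these counts include the setting with no cell filter, which removed 0 cells. Ratios within a library batch repeat those without EA05 for endocrine against Neurog3 and those without EA02 for E17.5, so they count again. Thinning each cell to 50000 counts and leaving out the proliferation lists kept every share of cells run that way within its interval. Depth limits the duct group most, where 3 counts are 0.103 CPM. The cause was not tested for any change below unless the setting itself shows it.

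For the Notch list against duct, the median was -0.19 with no gene filter. Within the library batch, the endocrine against Neurog3 comparison gave 0.10 for the progenitor list, -0.14 for Iapp and 0.10 for Btbd17. Within the batch and well rows A, B, E and F it gave 0.16 for the progenitor list, -0.56 for hormones, -0.79 for Dbpht2, -4.95 for Gcg (resting on row E of EA03), -1.48 for Slc7a2, 0.0211 for Hes6 and 0.11 for Btbd17. Within well rows C and G it gave -0.0402 for Cpa1, 0.0447 for Pax4, 0.67 for Ptprk and 0.40 for Ttll6. Within the batch without rows D and H it gave 0.11 for the progenitor list and 0.11 for Btbd17. For E17.5 against EA02 without rows D and H, hormones were 0.65, the progenitor list -0.50, Ins2 0.66, Ins1 0.16, Iapp 1.16 and Resp18 1.005. At E17.5 the progenitor list was 1.99 within the batch when its members were chosen again by level there. In Fev precursor-like cells the endocrine transcription factors were -0.0429 with DESeq2 size factors and -0.00882 without Rn45s.

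Leaving out 1 plate at a time gave, for endocrine against Neurog3, -1.76 (without EA02) to 0.10 (without EA05) for the progenitor list, -0.14 (without EA05) to 1.54 (without EA02) for Iapp and -3.05 (without EA02) to 0.10 (without EA05) for Btbd17. For E17.5 it gave -0.44 (without EA05) to 1.99 (without EA02) for the progenitor list and -1.46 (without EA02) to 0.21 (without EA05) for Iapp. Within Fev precursor-like cells granule genes gave -0.14 (without EA07) to 2.96 (without EA05), within progenitor-like cells -0.0261 (without EA07) to 2.84 (without EA06), and within beta-like cells the maturation list gave -0.18 (without EA07) to 1.007 (without EA06) and Pdx1 -0.0141 (without EA07) to 1.48 (without EA05). Endocrine transcription factors in progenitor-like cells gave 0.45 (without EA07) to 3.24 (without EA02). All genes shifted in these settings too. Without EA07 the median over all genes was -0.61 in progenitor-like, -0.24 in Fev precursor-like and -0.47 in beta-like cells. Without EA02 it was 3.16 in progenitor-like cells, where E15.5 held 1 such cell.

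With the level that makes a cell positive 10 times higher, Neurog3-positive cells were 41.9% (E17.5), cycling cells 43.9% (duct), cells with 2 hormones 0.699%, 1.27% and 0.775% (Neurog3, endocrine and E17.5), insulin 9.09% (Neurog3), Sst 2.80% and 6.20% (Neurog3 and E17.5), Ppy 0.699%, 0.637% and 0.775% (Neurog3, endocrine and E17.5) and Ghrl 0.699% and 1.27% (Neurog3 and endocrine). With it 10 times lower, cells with 2 hormones were 13.99%, 22.3% and 19.4% (Neurog3, endocrine and E17.5), insulin 23.1%, 32.5% and 23.3% (Neurog3, endocrine and E17.5) and Ppy 14.7%, 17.8% and 12.4% (Neurog3, endocrine and E17.5). A Y-linked gene was found in 47.9% of EA01 at 5 CPM, and in 20.8% of EA02 and 18.2% of EA04 at 100 CPM, where Xist was found in 79.2% of EA07. Over left-out plates the ranges were 8.24% (without EA02) to 59.7% (without EA05) in the endocrine group for Neurog3, 0% (without EA02) to 2.78% (without EA05) in the endocrine group for cycling, 1.43% (without EA01) to 8.22% (without EA03) in the Neurog3 group for 2 hormones, 11.1% (without EA05) to 32.9% (without EA02) in the endocrine group for insulin, 1.43% (without EA01) to 10.96% (without EA03) in the Neurog3 group for Sst and 8.33% (without EA06) to 24.6% (without EA07) in the E17.5 group for Ghrl.

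At resolution 0.5, Fev precursor-like cells were 0%, 0% and 0% (Neurog3, endocrine and E17.5), progenitor-like 55.2%, 27.4% and 6.98% (Neurog3, endocrine and E17.5), alpha-like 20.2% (E17.5), beta-like 5.59% (Neurog3), delta-like 7.69% (Neurog3) and epsilon-like 0%, 0% and 0% (Neurog3, endocrine and E17.5). At resolution 2, Fev precursor-like cells were 19.1% (endocrine) and alpha-like 10.5%, 23.6% and 10.9% (Neurog3, endocrine and E17.5). With 1000 variable genes, alpha-like cells were 19.4% (E17.5), duct-like 0% (endocrine) and epsilon-like 0%, 0% and 0% (Neurog3, endocrine and E17.5); with 4000, alpha-like cells were 12.4% (E17.5), duct-like 0% (endocrine) and epsilon-like 0%, 0% and 0% (Neurog3, endocrine and E17.5). Over 20 seeds and cell orders the lowest Fev precursor-like shares were 0% and 0% (Neurog3 and endocrine), and the highest shares were Fev precursor-like 16.6% (endocrine), progenitor-like 55.9% and 28.03% (Neurog3 and endocrine) and duct-like 6.99% and 4.46% (Neurog3 and endocrine). Without well rows D and H, cells with 2 hormones were 1.49% (Neurog3), Fev precursor-like 0% and 0% (Neurog3 and endocrine) and duct-like 0% (endocrine).

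Clustering again without each plate gave ranges of 0% (without EA01) to 48.3% (without EA07) in the Neurog3 group, 0% (without EA01) to 37.6% (without EA07) in the endocrine group and 19.4% (without EA02) to 41.7% (without EA06) in the E17.5 group for Fev precursor-like, 23.8% (without EA07) to 60% (without EA01) in the Neurog3 group, 5.88% (without EA02) to 51.4% (without EA05) in the endocrine group and 5.26% (without EA07) to 18.6% (without EA04) in the E17.5 group for progenitor-like, 0% (without EA02) to 1.39% (without EA05) in the endocrine group for acinar-like, 3.50% (without EA04) to 23.8% (without EA06) in the Neurog3 group, 5.56% (without EA05) to 42.04% (without EA06) in the endocrine group and 1.39% (without EA06) to 26.3% (without EA07) in the E17.5 group for alpha-like, 11.2% (without EA06) to 20.3% (without EA05) in the Neurog3 group, 20.8% (without EA05) to 31.8% (without EA02) in the endocrine group and 6.98% (without EA03) to 15.504% (without EA05) in the E17.5 group for beta-like, 0% (without EA01) to 6.29% (without EA06) in the Neurog3 group and 8.53% (without EA01) to 15.8% (without EA07) in the E17.5 group for delta-like, 0% (without EA01) to 8.22% (without EA03) in the Neurog3 group and 0% (without EA02) to 3.82% (without EA03) in the endocrine group for duct-like and 0% (without EA06) to 7.14% (without EA01) in the Neurog3 group, 0% (without EA06) to 5.88% (without EA02) in the endocrine group and 0% (without EA07) to 17.1% (without EA01) in the E17.5 group for epsilon-like cells.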

Other observations

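The tests in this part were chosen after the result was seen. The insulin-positive cells of well rows D and H of plates EA01 to EA03 (11 cells) were set beside those of plate EA05 (28 cells). The 2 sides were taken as different library batches and differed in depth. Median counts were 272206 in the 15 cells of these rows and 620338 in the cells of EA05. Ucn3, a gene of mature beta cells, was at 390.0 against 5.56 CPM, the prolactin receptor gene Prlr at 367 against 0 CPM, and G6pc2, a glucose-6-phosphatase subunit gene, at 2937 against 718 CPM. Chga was at 8565 against 476 CPM and Sst at 18315 against 223 CPM. The imprinted genes Nnat (13.3 against 4749.9 CPM) and Dlk1 (0 against 187 CPM) were lower and Peg3 (1037 against 329 CPM) was higher; the imprinted list had 1 of 8 members over 2-fold higher and 5 lower (median -2.54, -8.02 to 1.64). The maturation list had 9 of 14 members over 2-fold higher and 4 lower (median 1.68, -1.66 to 2.79), and the adhesion and keratin list 2 of 12 members over 2-fold higher and 8 lower (median -1.29, -2.49 to -0.32).

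Cre was read at 10 CPM or more in 68 cells of E17.5 (52.7%, 43.7 to 61.6), with 42.1% in EA06 and 61.1% in EA07, and in 0 cells of the Neurog3, endocrine and duct groups. In these groups of E15.5, 3 cells would be 2.10%, 1.91% and 4.55%, and the exact intervals end at 2.55%, 2.32% and 5.44%. The tomato transgene was read at 10 CPM or more in 0 cells of E17.5, where 3 cells would be 2.33% and the exact interval ends at 2.82%.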
